A study of Mus musculus with 2 samples.

How the data were processed

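Single-cell RNA sequencing was compared between 2 libraries of mouse brain tissue carrying orthotopic G422 glioma, 1 from untreated control mice and 1 from long-term survivors (LTS). Per the labels' protocols, tissue was digested with collagenase and DNase, passed through a 40 µm filter and layered on a Percoll gradient. Cells were taken from the interphase between 70% and 37% Percoll, and libraries were made with 3' version 3 droplet chemistry. The number of animals behind each library is not given in the sources used here.

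The values used were UMI counts per gene and barcode, deposited without normalization. They were made with Cell Ranger 4, per the file headers. The genome build was mm10, per the submitters' processing notes, and the annotation release is not given in the sources used here. Both matrices listed all 6794880 barcodes of the chemistry and 27998 genes, so they were unfiltered and cells had to be called. Gene positions came from GENCODE M21 on the same build, matched by gene identifier.

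Barcodes were called as cells if they reached 10% of the 99th percentile of the 3000 barcodes with most UMIs. Barcodes of 500 or more UMIs were also called if their profile differed from that of barcodes with 1 to 100 UMIs, by a multinomial Monte Carlo test with 10000 draws at a false discovery rate of 0.01. Cells with under 300 genes or over 15% mitochondrially encoded UMIs were left out, which removed 1 and 696 control barcodes and 1 and 595 LTS barcodes. Scrublet marked 1 control cell and 26 LTS cells (0.0135% and 0.485%). A caller that marks under 0.5% of over 5000 cells was taken not to have worked, so no cell was removed as a doublet, and keeping its calls gives identical values. The calling step was tested on simulated barcodes and called 0.3% of 3000 empty ones, 500 of 500 small cells and 300 of 300 large cells.

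Both libraries were clustered together without batch integration, since library and group are the same. UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, with immunoglobulin and T cell receptor segments left out, gave 30 principal components. Leiden clustering at resolution 1 on 15 neighbours gave the clusters (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python 3.11.15, matplotlib 3.10.9).

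Cell type markers were fixed before the data were examined, while the rule that applies them was written afterwards. A class could name a cluster if at least 3 of its markers were found in 10% of the cells at 2 times the level in other cells, and among such classes the one with the highest mean log2 ratio of its markers was taken. The cluster stayed unnamed if another class had more markers among its top 10 genes, if its median doublet score was over 0.2, or if its UMIs were under 0.333 of the library's median with no own marker among the top 10. After the first pass a further condition was added: a named host cell type had to carry at least 10% of the Y-linked CPM of the immune clusters. This moved cluster 0, led by Postn and Mgp, from fibroblast-like to unnamed. Unnamed clusters with under 10% of the immune clusters' Ptprc CPM and without low UMIs were pooled as the unnamed non-immune cells. Comparing this pool with the named classes was also decided after the data were seen.

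There was 1 library per group, so no test between conditions was possible and no p-value is given. Shares carry exact binomial (Clopper-Pearson) 95% intervals and ratios of summed counts carry exact conditional intervals. The intervals of share ratios combine the outer ends of both binomial intervals and are wide for that reason. All intervals cover counting error only, not differences between animals or preparations. Those of summed counts treat each UMI as independent, so they leave out differences between the cells of a class as well. Counts were summed per class and library for classes with at least 100 cells in each, scaled to CPM, and compared as log2 ratios of LTS over control with a pseudocount of 5 CPM. For the 21 gene lists fixed beforehand, the median log2 ratio of members with at least 20 CPM in either library was taken. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these libraries only. The counting interval of a median came from 1000 Poisson draws of its members' counts. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which left out 3 of 100 control and 18 of 495 LTS T cell-like cells.

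Genes were named by a rule fixed beforehand. Per class it takes the 6 genes with the largest and the 6 with the smallest log2 ratio, among genes with at least 50 CPM and a UMI in at least 10% of cells in the library where they are higher. They also need at least 0.1 of the highest CPM of any compared class there. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and receptor segment genes and unnamed models were left out. From each list the 2 members with the largest and the 2 with the smallest ratio could be named, and 7 T cell genes and 3 myeloid genes were always reported. Some genes that the rule takes are not reported here. T cell receptor constant genes, immunoglobulin constant genes, Trdc and Clec7a are not analysed here, nor is Itgam, whose symbol stands for more than 1 feature.

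Free RNA was measured in barcodes of 200 to 999 UMIs not called as cells, 53551 in control and 44326 in LTS, with a mean of 616 and 413 UMIs. Taking this amount off each cell would remove 20.3% and 11.2% of the UMIs of T cell-like cells, 10.3% and 4.93% of microglia-like cells, 18.0% and 6.83% of monocyte-like cells, and 2.92% and 0.987% of the unnamed non-immune pool. Such barcodes could also hold damaged cells, so the amount is an estimate.

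Class sums were tested on simulated counts drawn from the control profile with 200 genes changed. In the T cell-like class, over 3203 genes, 92.0% of genes changed by a factor of 2 and 86.0% of those changed to a level of 0.25 came within 0.5 on the log2 scale. Counting intervals covered the true ratio for 96.0% of 500 unchanged genes. Of 100 lists of 15 unchanged genes, 1 had a percentile under 1 or over 99 and 6 one under 5 or over 95.

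The alternatives tried were cell calling by the UMI threshold alone or at 1000 UMIs, mitochondrial limits of 10% and 25%, Leiden resolutions of 0.5 and 2, 3000 variable genes with 50 components, and immune cells as the denominator. For expression they were median-of-ratios scaling, the mean over cells of each cell's CPM, a pseudocount of 1 CPM, 5% of UMIs taken off as free RNA, and lists without a CPM minimum. Unthinned cells and a limit of 3 proliferation genes were tried for shares of cells with a UMI and of cycling cells. Further alternatives were added after seeing the data, namely free RNA taken off at the measured amount, doublet scores over 0.25 left out, microglia-like cluster 1 alone, and T cell-like cells with a Cd3 UMI and without a C1q UMI.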

Results

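Transcripts of single cells were counted in 2 libraries from Kunming mice bearing G422 glioma, a mouse glioma line grown in the brain. The control library came from untreated mice 7 days after inoculation. The LTS library came from mice that survived more than 100 days after combined therapy and were inoculated again on the opposite side. The sources used here leave open which inoculation its day 7 counts from. The question was how the cells at the tumour site differ between a first tumour and tissue of mice that survived an earlier one. The libraries held 165796852 (control) and 149413534 (LTS) UMIs. After filtering, 7388 control cells with a median of 16639 UMIs and 5362 LTS cells with a median of 12380.5 UMIs were kept. With 1 library per group there was no replicate check on any difference below, and every interval covers counting error only.

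T cell-like cells made up a larger share of the LTS library. They were 495 of 5362 LTS cells (9.23%, 95% interval 8.47 to 10.04) and 100 of 7388 control cells (1.35%, 1.10 to 1.64), a ratio of 6.82 (5.15 to 9.10). B cell-like cells were 1.34% (1.05 to 1.69) in LTS and 0.325% (0.208 to 0.483) in control. Microglia-like cells, the brain's resident macrophages, were 11.9% (11.01 to 12.8) and 10.3% (9.58 to 10.97). Monocyte-like cells, which enter tissue from the blood, were 4.27% (3.75 to 4.85) and 5.67% (5.15 to 6.22). The unnamed non-immune pool, whose clusters had little Ptprc and either too few markers for a name or, in cluster 0, fibroblast markers without the host's Y-linked transcripts, was 47.6% (46.2 to 48.9) of LTS and 71.2% (70.2 to 72.3) of control cells. With the UMI threshold alone as the calling rule, the log2 ratio of its share was -0.042 and not -0.58. That threshold was 9339 UMIs in LTS and 5385 in control, and the pool was then 84.6% of LTS and 87.1% of control cells.

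Among the 1451 LTS and 1320 control cells of named immune classes, T cell-like cells were 34.1% (31.7 to 36.6) in LTS and 7.58% (6.21 to 9.14) in control, a ratio of 4.50 (3.47 to 5.90). With this denominator monocyte-like cells were 15.8% in LTS and 31.7% in control, and microglia-like cells were 43.8% and 57.4%, so the order of the microglia-like shares turned. T cell-like cells took more of this denominator in LTS, which by itself lowers the shares of the other classes there. Conventional dendritic cell-like cells were 1.31% and 1.44%, with overlapping intervals. Of all cells kept, choroid plexus epithelium-like cells were 1.49% (1.18 to 1.85) in LTS and 0.203% (0.114 to 0.335) in control, a ratio of 7.35 (3.54 to 16.3), from 80 and 15 cells. Oligodendrocyte-like cells were 0.242% and 0.149%, from 13 and 11 cells, and endothelial cell-like cells 1.34% and 1.87%. Clusters left unnamed for low UMIs, high doublet scores or missing markers held 22.3% of LTS and 8.69% of control cells. Among them cluster 3 held 15.8% of LTS and 2.60% of control cells, at medians of 579.5 and 1327 UMIs. Clusters 15 and 18, with 9 microglia and 7 plasmacytoid dendritic cell markers, were left out of the named immune classes as well. The gradient sets which cells are recovered, so shares of all cells are not shares of the tissue.

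**Figure D1:**
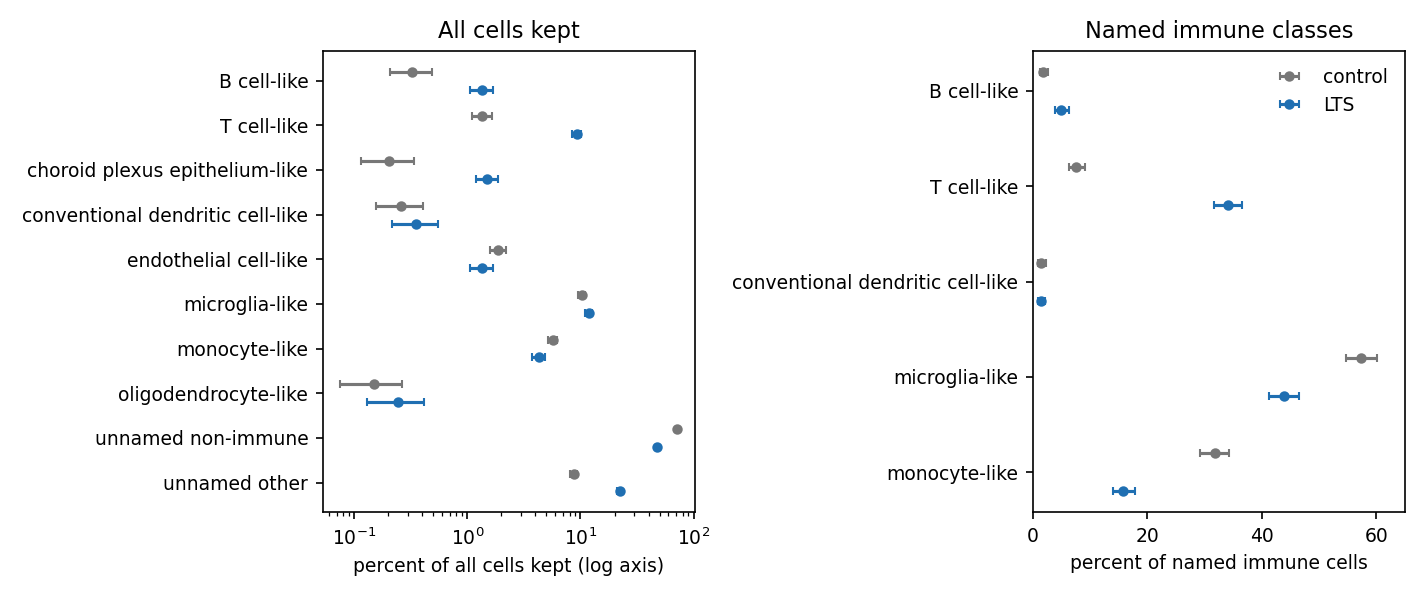
Share of each cell class in percent of all cells kept (left, log axis) and of named immune cells (right), for control (grey) and LTS (blue), with exact binomial 95% intervals that cover counting error only. T cell-like cells were 9.23% of LTS and 1.35% of control cells.

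Within the T cell-like class, transcripts of Cd8a or Cd8b1, the chains of the co-receptor of cytotoxic T cells, were found in more of the LTS cells. After thinning to 1000 UMIs, 219 of 477 LTS cells (45.9%, 41.4 to 50.5) and 16 of 97 control cells (16.5%, 9.73 to 25.4) had such a UMI. Without thinning the shares were 54.5% and 21%. Cd4, the co-receptor of helper T cells, was found in 7.97% (5.70 to 10.8) and 7.22% (2.95 to 14.3). Foxp3, the transcription factor of regulatory T cells, was found in 1.47% (0.592 to 3.0) and 4.12% (1.13 to 10.2), and Gzmb in 17.4% (14.1 to 21.1) and 27.8% (19.2 to 37.9). The thinned intervals of Cd4, Foxp3 and Gzmb all overlapped between the libraries. Without thinning the Gzmb shares were 30.3% (26.3 to 34.6) and 36.0% (26.6 to 46.2), with overlapping intervals as well. In the unnamed non-immune pool the thinned share with Cd8a or Cd8b1 was 0.157% in LTS and 0.0190% in control, at median depths of 40980.5 and 20148 UMIs against 3200 and 2073 in T cell-like cells. Without thinning the pool's shares were 2.70% and 0.285%.

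The control T cell-like cluster held a larger share of cells with natural killer transcripts. Ncr1 or Klrb1c, receptors of natural killer cells, were found in 10.3% (5.06 to 18.1) of thinned control cells and 1.26% (0.463 to 2.72) of LTS cells, and without thinning in 14 of 100 and 14 of 495. Cd3d, Cd3e or Cd3g, parts of the T cell receptor complex, were found in 56.7% (46.3 to 66.7) and 87.8% (84.6 to 90.6). Cells with Ncr1 or Klrb1c and without Cd3 were 7.22% (2.95 to 14.3) and 1.05% (0.341 to 2.43), so most cells without a Cd3 UMI had no UMI of these 2 genes either. Both values bear on every comparison within this class.

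**Figure D2:**
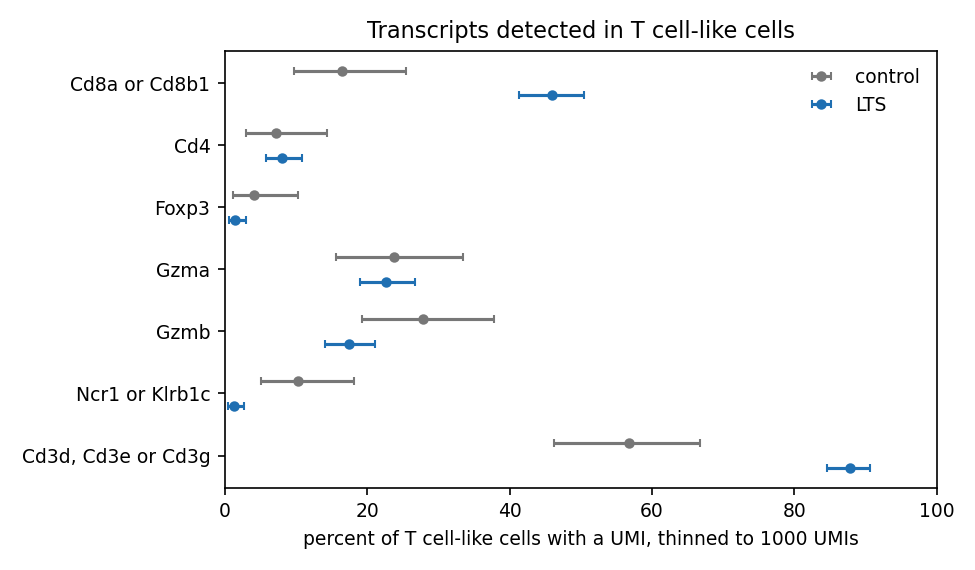
Percent of T cell-like cells with a UMI of the named genes after thinning each cell to 1000 UMIs, for control (grey) and LTS (blue), with exact binomial 95% intervals that cover counting error only. Cd8a or Cd8b1 was found in 45.9% of LTS and 16.5% of control cells.

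In summed counts of T cell-like cells, genes of cytotoxic function were mostly higher in LTS. The cytotoxic effector list had a median log2 ratio of 0.68 (0.51 to 0.98), above nearly all matched random lists (percentile 100), with 11 of 13 measured members higher, and 0.42 when cells weighed equally. Ccl5, a chemokine of effector T cells, was 3.65-fold higher (3.36 to 3.98) and Gzmk, a granzyme, 3.68-fold (2.24 to 6.52). Gzmb, the granzyme of armed killer cells, went the other way, at 316 CPM in LTS and 740.2 CPM in control (2.34-fold lower, 1.997 to 2.73). Cx3cr1, which natural killer cells and microglia also express, had a log2 ratio of -1.43. Cd3d, Cd3e and Cd3g, named here after their values were seen, had log2 ratios of 1.23, 1.17 and 1.25 in the same sums, above the medians of the cytotoxic and residency lists. The list medians are not corrected for this difference.

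The tissue residency list had a median of 0.50 (0.30 to 0.75, percentile 100), with 11 of 12 members higher, and 0.26 in cells with a Cd3 UMI and without a C1q UMI, a selection chosen after seeing the data. Itgae, the integrin that binds epithelial cadherin, was at 173 CPM in LTS and 23.03 CPM in control, from 317 and 7 counts (7.52-fold, 3.61 to 18.9), and 1 control cell held 42.9% of the control counts. Cxcr6, a chemokine receptor of resident T cells, was 2.80-fold higher (2.18 to 3.66), while Rgs2 had a log2 ratio of -0.82. Cd8a (ENSMUSG00000053977), on chromosome 6 from 71373427 to 71379173 (mm10), was 3.02-fold higher (2.22 to 4.21). Il7r, the interleukin-7 receptor of long-lived T cells, was 5.998-fold higher (3.66 to 10.6) and Ltb 2.58-fold (2.12 to 3.17), whereas Ccr7, a chemokine receptor of lymph node homing, had a log2 ratio of -1.66. The naive and central memory list, which holds Il7r, Ltb and Ccr7, had a median of -0.45 (-0.90 to 0.04, percentile 10.4). It was -0.63 (percentile 4.96) with free RNA taken off, -0.87 when cells weighed equally and -0.30 with median-of-ratios scaling.

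The regulatory T list was lower in LTS, with a median of -1.19 (-1.47 to -0.87, percentile 0) and 9 of 9 measured members lower. Ikzf2, the regulatory T cell factor Helios that natural killer cells also express, was 3.29-fold lower (2.55 to 4.22) and Tnfrsf4 3.42-fold lower (2.50 to 4.65). Foxp3 rested on 28 LTS and 12 control counts (2.58-fold lower, 1.20 to 5.24), and Ctla4, an inhibitory receptor, was 1.77-fold lower (1.17 to 2.64). The checkpoint and exhaustion list had a median of 0.10 (-0.26 to 0.42, percentile 88.6), with 5 of 10 members on either side, or 7 higher and 3 lower relative to the median of all genes. Among them Havcr2 had a log2 ratio of 1.58, from 3 control counts (3.98-fold, 1.31 to 19.8), and Nr4a2 one of -1.15. Pdcd1, the gene of PD-1, was at 78.1 and 62.5 CPM (1.25-fold, 0.772 to 2.14), and Ifng at 72.1 and 46.1 CPM (1.57-fold, 0.901 to 2.94), neither of which could be told from 1 at this depth, and the direction of both turned in cells with a Cd3 UMI and without a C1q UMI. Cd4 was likewise open (1.53-fold, 0.971 to 2.52).

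Interferon-induced genes were lower in LTS T cell-like cells, with a list median of -0.88 (-1.01 to -0.55, percentile 0) and 18 of 20 members lower, or 15 relative to the median of all genes. Oasl2 and Rsad2, both antiviral genes, had log2 ratios of -2.23 and -1.73. The list stayed lower with free RNA taken off at the level of uncalled barcodes. Genes of the unnamed non-immune pool gave larger amounts of its RNA, and more in control than in LTS T cell-like cells. Isg15 and Ifi44 were among the top 10 genes of the pool's clusters 7 and 11. How much of the interferon difference RNA in such amounts would give was not tested. The MHC class I list was at 0.33 (0.21 to 0.48, percentile 99.3), with H2-D1 at 0.56 and H2-Q7 at -0.42. Its median was 0.20 with free RNA taken off and 0.18 (percentile 92.4) in cells with a Cd3 UMI and without a C1q UMI. The MHC class II list was at -1.75, but 1 cell held 45.3% of the control and 1 cell 67.3% of the LTS counts of H2-Ab1. It was -3.66 with cells called at 1000 or more UMIs and -3.83 in cells with a Cd3 UMI and without a C1q UMI. The median ratio of all genes in this class was -0.15. Relative to it the cytotoxic, residency, regulatory and interferon lists stood at 0.83, 0.65, -1.04 and -0.73.

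The 6 genes with the largest ratios in this class were Gstm5, Itgae, Il7r, Dkkl1, Cdh1 and AA467197. Of these Gstm5 and Dkkl1 rested on 1 and 2 control counts (16.3-fold, 2.85 to 649, and 8.38-fold, 2.26 to 70.2). Cdh1, the epithelial cadherin that Itgae binds, was 6.86-fold higher (2.29 to 33.7) and AA467197 4.84-fold (2.85 to 8.93). The 6 with the smallest ratios were Scx, Col4a2, Snx9, Mgp, Mmp14 and Snhg18, from -2.47 for Scx to -2.26 for Snhg18. All 6 were also found in uncalled control barcodes, at 40.3 CPM for Col4a2 to 389.7 CPM for Mgp, and 1 control cell held 59.5% of the Mgp counts. Other list medians in the class were -0.03 for T costimulation (0.12 relative to all genes, and -0.82 in cells with a Cd3 UMI and without a C1q UMI), -0.41 for B activation, -0.23 for homeostatic microglia, -0.59 for disease-associated microglia, -0.18 for immunosuppressive myeloid, -0.73 for chemokine, -1.51 for complement, -0.58 for glycolysis and hypoxia, -0.56 for dissociation stress, -0.17 for mitochondrially encoded and 0.88 for sex-linked genes. In cells with a Cd3 UMI and without a C1q UMI, the chemokine median turned to 0.027, homeostatic microglia was at 0.37 and dissociation stress at -0.25. In the whole class, homeostatic microglia was at -0.45 with free RNA taken off, and disease-associated microglia at -0.30 when cells weighed equally. The mitochondrially encoded median turned to 0.071 when cells weighed equally and to 0.069 with cells called at 1000 or more UMIs.

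Microglia-like cells of the LTS library had more MHC class II transcripts, which encode the proteins that present antigen to helper T cells. The list median was 1.04 (0.86 to 1.20, percentile 100), with 8 of 8 measured members higher. It was 1.65 when cells weighed equally and 0.52 without a CPM minimum. H2-Aa (ENSMUSG00000036594), on chromosome 17 from 34282744 to 34287823 (mm10), was 3.07-fold higher (2.84 to 3.32), Cd74 2.51-fold (2.41 to 2.60), H2-Eb1 2.40-fold (2.25 to 2.57) and H2-Ab1 2.26-fold (2.12 to 2.41). The homeostatic microglia list had a median of 0.43 (0.37 to 0.50, percentile 100), with 14 of 14 members higher. These ran from Tgfbr1, a receptor of TGF-beta, at 1.96-fold (1.76 to 2.18) and Selplg at 1.77-fold (1.65 to 1.89) to P2ry13 at 1.13-fold and Mef2c at 1.11-fold. The dissociation stress list, genes that tissue handling can induce, was higher in the same cells, at 0.26 (0.21 to 0.33, percentile 100) with 13 of 18 members higher.

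Different clusters held much of this class in the libraries. Cluster 16 held 236 of 636 LTS and 10 of 758 control microglia-like cells, and cluster 1 the rest. A cluster found mostly in 1 library can reflect that library as well as a cell state. In cluster 1 alone, chosen after seeing the data, the MHC class II median was 0.32 (percentile 100) and the homeostatic median 0.14 (percentile 98.6), with 12 of 14 members higher. The dissociation stress median was 0.056 (percentile 70.2) in these cells, and P2ry13 was among the 2 homeostatic members that were lower there.

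The disease-associated microglia list, genes of activated microglia, was at 0.14 (0.10 to 0.20, percentile 99.2), with Itgax at 0.46, Trem2 at 0.39 and Spp1 at -0.24, and turned to -0.13 when cells weighed equally. Interferon response was at -0.11, MHC class I at 0.09, checkpoint and exhaustion at 0.36, tissue residency at 0.20, B activation at 0.25, immunosuppressive myeloid at 0.36, inflammatory cytokine at 0.07, chemokine at 0.02, complement at 0.18, glycolysis and hypoxia at -0.09, mitochondrially encoded at -0.15 and sex-linked at 0.26. Several of these depended on how cells were weighed. With equal weight, interferon response was at -0.40 with 0 of 21 members higher, MHC class I at -0.031, checkpoint and exhaustion at 0.70, tissue residency at 0.32, immunosuppressive myeloid at 0.12, inflammatory cytokine at -0.051, chemokine at -0.18, glycolysis and hypoxia at -0.32 and sex-linked at 0.53. In cluster 1 alone, interferon response was at 0.051, checkpoint and exhaustion at 0.11, tissue residency at 0.072, inflammatory cytokine at 0.18, chemokine at 0.15, glycolysis and hypoxia at 0.013, mitochondrially encoded at -0.090 and sex-linked at 0.095. Cd274, the gene of PD-L1, was 1.36-fold higher (1.12 to 1.66). Arg1 had 18 control counts, 83.3% of them in 1 cell, and 0 LTS counts. The other genes with the largest ratios were Rgs2 (1.01) and Col27a1 (1.17). Those with the smallest were Pbld2, Vim, Rhox5, S100a11, Snhg9 and Anxa1, from -1.63 to -1.39. All 6 were abundant in uncalled control barcodes, from 251 CPM for Snhg9 to 4888 CPM for Vim.

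Monocyte-like cells of LTS also had more MHC class II transcripts, with a list median of 0.42 (0.24 to 0.46, percentile 100) and 9 of 9 members higher, among them H2-Eb1 at 0.53, H2-Aa at 0.51 and H2-Ab1 at 0.42. With free RNA taken off the median was 0.23. The disease-associated microglia list was at 0.39 (0.25 to 0.42, percentile 100) with 13 of 14 members higher. In it Itgax and Gpnmb were both at 0.54, while Spp1, which encodes osteopontin, was at -1.20. The 6 genes with the largest ratios were Cxcr4 (2.51-fold, 1.72 to 3.73), a chemokine receptor, Hvcn1, Ccl24, Plxnc1, Cd302 and Ass1 (1.94-fold, 1.47 to 2.58), and 1 LTS cell held 54.7% of the Ccl24 counts. Cenpv (-2.30), Rhox5, Pbld2, Tpm2, Psph and Fscn1 (-1.67) had the smallest, at 112 to 1114 CPM in uncalled control barcodes. Cd274 was 1.41-fold higher (1.08 to 1.85), and Arg1 was at 0.914-fold (0.680 to 1.22). Ccl7, which attracts monocytes, had a log2 ratio of -1.74 and Ifit1 one of -0.67.

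Among the other lists in monocyte-like cells, cytotoxic effector was at 0.42 (percentile 99.7) with 3 of 4 measured members higher, and B activation at 0.36 (percentile 99.4) with 5 of 5 higher. With free RNA taken off they were at 0.25, with 2 of 4 higher, and 0.24. With cells called at 1000 or more UMIs the cytotoxic median was 0.026, and its members with the largest ratios, Gzma and Ccl5, are T cell genes. Interferon response was at 0.01, MHC class I at 0.21, checkpoint and exhaustion at 0.04, naive and central memory at 0.10, tissue residency at 0.17, homeostatic microglia at 0.23, immunosuppressive myeloid at 0.11, inflammatory cytokine at 0.08, chemokine at -0.12, complement at 0.23, glycolysis and hypoxia at -0.17, dissociation stress at 0.12 and mitochondrially encoded at -0.16. With free RNA taken off, interferon response was at -0.16 (percentile 3.02) with 18 of 21 members lower, MHC class I at 0.091, homeostatic microglia at 0.049, complement at 0.065, chemokine at -0.27, glycolysis and hypoxia at -0.25 and mitochondrially encoded at -0.28. The medians of checkpoint and exhaustion, naive and central memory, tissue residency, immunosuppressive myeloid, inflammatory cytokine and dissociation stress turned below 0, at -0.13, -0.073, -0.011, -0.055, -0.059 and -0.040.

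**Figure D3:**
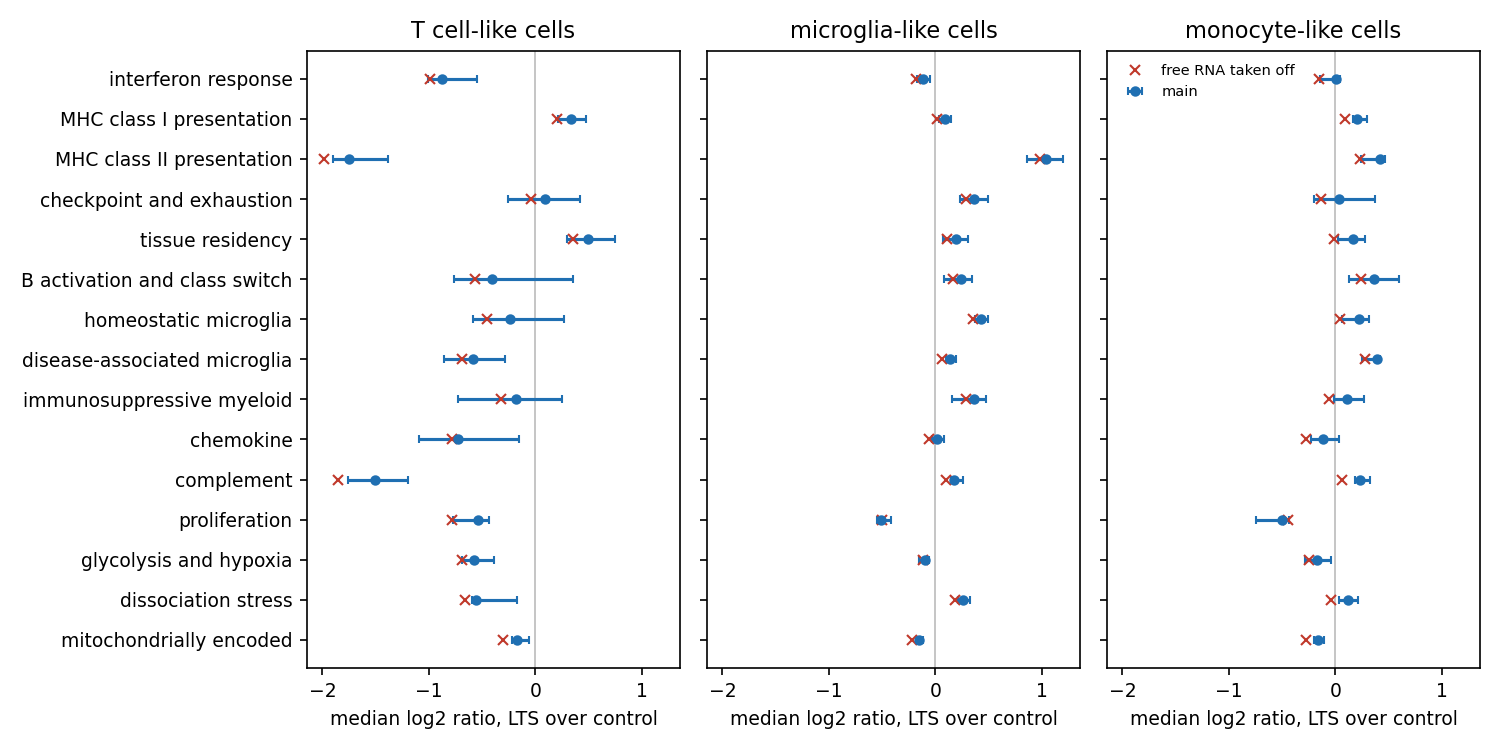
Median log2 ratio of LTS over control for gene lists measured in T cell-like, microglia-like and monocyte-like cells (blue points) with counting intervals from Poisson draws, and the median after free RNA was taken off (red crosses). MHC class II presentation stood at 1.04 in microglia-like and 0.42 in monocyte-like cells.

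The unnamed non-immune pool differed little between the libraries in the medians of most fixed lists, though some leaned to 1 side. Proliferation had 17 of 19 members lower in LTS (percentile 0.63), mitochondrially encoded 9 of 11 (percentile 0.12) and interferon response 8 of 12 (percentile 3.05). Interferon response was at -0.06 (-0.09 to -0.02), MHC class I at -0.03, proliferation at -0.09, glycolysis and hypoxia at 0.02, naive and central memory at 0.01, tissue residency at 0.08, homeostatic microglia at -0.10, disease-associated microglia at -0.01, immunosuppressive myeloid at 0.03, chemokine at 0.05, dissociation stress at -0.04 and mitochondrially encoded at -0.13. Complement was at -0.97, on 3 genes that microglia express. It was -1.96 with 5% of UMIs taken off as free RNA and -0.90 with free RNA taken off at the measured amount. Single genes stood further apart. Pbld2 (ENSMUSG00000020072), on chromosome 10 from 63024315 to 63058813 (mm10), was 3.06-fold lower in LTS (3.02 to 3.11), at 201 and 614.9 CPM. Snhg9, a small nucleolar RNA host gene, was 2.95-fold lower (2.86 to 3.04), followed by Dennd5b, Sag, Exoc1 and Mpv17l at -1.31 to -1.19. Hist1h2ap, a histone H2A gene, was 1.47-fold higher (1.45 to 1.48), and Mapk1ip1l, Tomm22, Plaur and Dynlt1f were at 0.41 to 0.37. Hist1h2ap has near-identical copies that counting can confuse.

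Genes of cell division were lower in LTS in T cell-like, microglia-like and monocyte-like cells. The proliferation list had medians of -0.54 (-0.78 to -0.44, percentile 0.490) in T cell-like, -0.51 (-0.55 to -0.42, percentile 0) in microglia-like and -0.50 (-0.74 to -0.43, percentile 0) in monocyte-like cells, with 18 of 19, 19 of 19 and 18 of 18 members lower. In microglia-like cells Top2a and Rrm2 were at -0.70 and -0.79, and in monocyte-like cells Tyms and Rrm2 at -1.15 and -1.23. Cells with UMIs of 2 or more of these genes after thinning were 20.5% (17.0 to 24.5) of LTS and 52.6% (42.2 to 62.8) of control T cell-like cells. The shares were 28.3% and 43.4% in microglia-like, 10.7% and 22.1% in monocyte-like, and 52.9% and 58.3% in unnamed non-immune cells. In B cell-like cells they were 10% (4.12 to 19.5) of 70 and 39.1% (19.7 to 61.5) of 23, and without thinning 43.1% (31.4 to 55.3) and 62.5% (40.6 to 81.2), with overlapping intervals. In endothelial cell-like cells they were 34.8% (23.7 to 47.2) and 53.3% (44.6 to 61.9), with overlapping intervals. Unthinned shares of T cell-like cells were 64.0% (59.6 to 68.3) in LTS and 73.0% (63.2 to 81.4) in control, with overlapping intervals. With 3 or more genes after thinning, monocyte-like shares were 3.56% (1.55 to 6.89) in LTS and 5.53% (3.54 to 8.18) in control, with overlapping intervals. The same genes were in the free RNA, which took a larger part of the control cells' UMIs, so no share of dividing cells is read from these values.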

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

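The tests of thinned depth, cluster 1 alone, Lyz2 and the free RNA share of proliferation genes were set down before their results were seen, and the tests of the immune denominator and of MHC class II and proliferation genes with free RNA off afterwards. No test can separate the LTS condition from differences between single preparations, so each biological explanation stays untested. Earlier therapy, survival of more than 100 days and any host age that came with it belonged to the LTS library alone. No pattern below can be told apart from their effects.

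Barcodes not called as cells are compared with each other nowhere else, and 3 genes chosen after the values were seen were above the level in the control library there. Ttr, made by choroid plexus, was 13.2 times as high in LTS (396 and 30.0 CPM). Mbp, a myelin gene, was 11.6 times as high (40.5 and 3.49 CPM), and Gzma, a granzyme of T and natural killer cells, 11.2 times (18.0 and 1.61 CPM).

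The first pattern is the higher T cell-like share in LTS. Whether T cells of under 1000 UMIs were left uncalled in control for lower depth per cell stays open. Thinning the LTS library to 49.2% of its UMIs and keeping cells of 500 or more UMIs left a ratio of 7.85 (5.92 to 10.5). LTS T cell-like cells had a median of 3200 UMIs, and 476 of 495 passed that limit. Loss at the limit was thus small, but the ambient test, which could also leave cells uncalled, was not run again. Calling all barcodes of 1000 or more UMIs, without that test, gave 475 LTS and 93 control T cell-like cells, a ratio of 8.75. This argues against a loss of control T cells of 1000 or more UMIs to the ambient test. Fewer non-immune cells would raise the other classes alike, but among named immune cells the T cell-like ratio was 4.50 (3.47 to 5.90). Over all cells kept the ratio was 0.753 (0.602 to 0.940) for monocyte-like and 1.16 (1.003 to 1.33) for microglia-like cells. A response of survivors to a second tumour may give such a share, and so may the age of the lesion, the yield of the gradient or the piece of tissue taken, and choroid plexus epithelium-like cells had a ratio of 7.35 (3.54 to 16.3).

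The second pattern is the higher MHC class II expression of LTS microglia-like cells. Monocyte-like RNA is argued against, since Lyz2 was higher by only 16.3% of what the H2-Aa difference would need, and lower free RNA in LTS likewise, since the median was 0.98 with free RNA taken off. Cd74 and H2-Aa were also among the top 10 genes of B cell-like cells and of cluster 18. RNA from those cells was not tested. Cluster 16, almost absent from control, may carry a large part of the MHC class II difference, since the median in cluster 1 alone was 0.32, between the limits set beforehand. The clusters were built from the same expression values, however. Cd74 of the MHC class II list and Btg2 of the dissociation stress list were among the top 10 genes of cluster 16. Leaving that cluster out could thus lower both medians by construction. Whether that cluster is a state of LTS microglia or tissue further from the tumour, or follows tissue handling, remains open, since the dissociation stress median was 0.26 in the class and 0.056 in cluster 1 alone.

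The third pattern is the lower proliferation list in T cell-like, microglia-like and monocyte-like cells of LTS. With free RNA taken off at the level of uncalled barcodes the median was -0.79 in T cell-like, -0.50 in microglia-like and -0.44 in monocyte-like cells, which argues against free RNA at that level as the whole source. Genes of the non-immune pool gave larger amounts, with a median over 7 genes of 37.1% of control T cell-like UMIs, 18.1% of microglia-like and 24.99% of monocyte-like, on which RNA of non-immune cells would give 63.2%, 42.3% and 104% of the difference. Single genes gave -0.389% to 553%, 17.0% to 103% and 75.3% to 204%, so RNA in such amounts and slower division cannot be told apart in any of these classes. That this spread decides was set only after the medians were seen, on which such RNA would have been argued against in microglia-like cells and would have accounted for the difference in monocyte-like cells.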

How the results depend on the processing

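The alternatives with a Cd3 selection, microglia-like cluster 1 alone, doublet scores and free RNA at the measured level were chosen after seeing the data. Of 183 alternative values for the 30 results that answer a comparison, 147 stayed within counting error, 34 moved further and 2 turned direction. Of 1026 for the 148 other results, 825 stayed, 192 moved and 9 turned. Only results whose counting interval excluded 0 are counted as turned, and the sign itself was kept by 179 of the 183 and 992 of the 1026. The cause was not tested except where the alternative's construction gives it. With the UMI threshold alone, the log2 share ratio was 2.24 for T cell-like cells (2.77 as reported) and -0.042 for the unnamed non-immune pool (-0.58). The T cell-like value there rested on 30 LTS and 13 control cells. At 1000 or more UMIs it was 0.51 for microglia-like cells (0.21) and -0.25 for the pool, the T proliferation median was -0.40 and the T mitochondrially encoded median turned to 0.069. Over immune cells alone the share ratio was 2.17 for T cell-like and -1.01 for monocyte-like cells (-0.41), and turned to -0.39 for microglia-like cells. Median-of-ratios scaling gave 0.48 for T MHC class I, -0.39 for T proliferation and 0.43 for monocyte disease-associated genes. With cells weighed equally, T cytotoxic was 0.42, T proliferation -0.79, microglia MHC class II 1.65, homeostatic 0.80 and proliferation -0.65, and monocyte proliferation -0.81. There microglia disease-associated genes turned to -0.13, microglia MHC class I to -0.031 and T mitochondrially encoded genes to 0.071. Free RNA taken off at the measured level gave 0.20 for T MHC class I, -0.79 for T proliferation, 0.36 for microglia homeostatic, 0.066 for microglia disease-associated and 0.23 for monocyte MHC class II genes, and turned monocyte residency to -0.011 and monocyte stress to -0.040. T cell-like cells with a Cd3 and without a C1q UMI gave -1.21 for interferon, 0.18 for MHC class I and 0.26 for residency, and turned chemokine to 0.027, while T costimulation was -0.82 (-0.03 as reported) and homeostatic microglia 0.37 (-0.23). Cluster 1 alone gave 0.32 for MHC class II, 0.14 for homeostatic and -0.37 for proliferation genes, and turned interferon to 0.051, glycolysis to 0.013 and P2ry13 in microglia-like cells, log2 LTS over control, to -0.053. Without a CPM minimum microglia MHC class II was 0.52 and pool interferon -0.11, and with 5% of UMIs off pool proliferation was -0.11. The difference in cells with proliferation genes was -8.96 percentage points unthinned and -16.2 with 3 or more genes in T cell-like cells (-32.0 as reported), -1.97 with 3 or more in monocyte-like cells (-11.4) and -0.145 unthinned in the pool (-5.33). Keeping doublet calls equals the values as reported, since none were removed. No B cell-like class was found with the UMI threshold alone and no monocyte-like class either, so neither has a value there. No paired analysis was possible because each group had 1 library. Depth limits the control T cell-like values, at 303958 UMIs over 100 cells, and the control B cell-like shares, over 24 cells.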

Other observations

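The test of Y-linked transcripts was chosen after the values were seen. The unnamed non-immune pool lacked the Y-linked transcripts of Ddx3y, Eif2s3y, Kdm5d and Uty that the host's cells carried. Microglia-like cells had 140 CPM in LTS and 119 CPM in control and endothelial cell-like cells 94.3 and 81.4 CPM, whereas the pool had 0.899 and 0.992 CPM. Xist was at 0.103 and 0.108 CPM in the pool, so neither sex's transcripts marked it. A hypothesis is that the pool descends from the inoculated line and not from the host. Without cluster 0, whose placing used these genes, the pool's Y-linked CPM was 1.10% of that of endothelial cell-like cells. This reads again the low values that prompted the hypothesis, so it adds no support and the hypothesis stays open. Loss of the Y chromosome in host-derived tumour cells was not tested and would look alike.

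Pbld2 was lower in LTS in all 10 clusters of the pool, by 2.49 to 3.31 times, and Snhg9 by 2.23 to 3.69 times. Dennd5b, Sag, Exoc1 and Mpv17l were lower in all 10 clusters as well, Mpv17l by 1.56 to 3.05 times. A shift in the mix of these clusters alone would not give that, while a shift of cells within clusters was not examined. These genes were chosen as the pool's lowest in the same cells. Pbld2, Snhg9, Mpv17l and Dennd5b were also among the top 10 genes of cluster 12, which held 5.25% of control and 1.32% of LTS cells. The annotation puts Pbld2 on chromosome 10 and Snhg9 on chromosome 17. No explanation was tested.

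Of the T cell-like class, 49 control and 324 LTS cells had a Cd3 UMI and no C1q UMI. This selection does not take off RNA of the unnamed non-immune pool. In these cells, chosen after seeing the data, the cytotoxic effector median was 0.92 (percentile 100) with 9 of 14 members higher, the regulatory T median -1.24 (percentile 0), the interferon median -1.21 (percentile 0) and the T costimulation median -0.82 (percentile 0.330), with 3 of 8 members higher.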
